A study of Mus musculus with 24 samples.

How the data were processed

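CUT&Tag libraries were made from 3 sorted subsets of mouse small-intestinal ILC3s (CCR6+, NKp46+ and DN), with 100000 cells per library per the labels' protocols, from 2 genotypes and with antibodies to CFP1 and to H3K4me3. Genotype, subset, antibody and replicate number were taken from the sample titles. The labels give an age of 6 to 8 weeks, but their protocols also name aged and young mice and a culture medium, so the age and handling of these samples are not settled. All 24 libraries were mapped to a group, giving 12 groups of 2 libraries. The labels do not say whether the replicates, or the 3 subsets of one replicate number, came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

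Per the submitters' processing notes, the tools were fastp 0.19.7, Bowtie2 2.3.5.1, Picard (version not given), MACS2 2.2.7.1 and ChIPseeker 1.28.3, and the genome build was mm10. The roles and settings of these tools, any control library and the removal of duplicates are not given in the sources used here. The authors deposited 1 narrowPeak list per library. Each deposited list gives a peak's position and summit, its fold enrichment (a ratio), and the −log10 of its p-value and q-value. The deposited integer score was not used. The smallest −log10 q per list was 1.30 to 1.42, so every deposited peak has a q-value of at most 0.05. A fold enrichment is the authors' value for a peak within its own list, and it was used only to filter or rank peaks within that list. Because the lists hold no read or count totals, sequencing depth is unknown; a deeper library can give a longer list and wider peaks, and the absence of a peak means only that none was called at the depth of that library. Binomial confidence intervals (Wilson, 95%) and floors (3 counts of the total) are given for shares of genes and cover counting error only.

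Peaks on the 19 autosomes and the X chromosome were used. Protein-coding genes (21631) with start and end were taken from a RefSeq gene table of the mouse assembly GRCm38.p6, whose coordinates are those of mm10. The table holds no strand and no exons, so the planned window around the transcription start was replaced by windows of 1000 b on either side of both annotated gene ends. A gene counts as holding a peak in a library when a peak overlaps either window by 1 b or more. Both windows of all genes cover 2.98% of the span used, gene starts inside an annotated gene are missed, and 7048 genes (32.6%) share a window with another gene, so a peak there counts for each of them. No genome sequence was used here, so CpG content was not measured. Coordinates are 1-based in mm10.

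For each antibody, log2 peak numbers, log2 median peak widths and the share of CFP1 peaks overlapping H3K4me3 by 1 b or more were compared between genotypes with an exact two-sided permutation of the genotype labels within each subset (216 arrangements, smallest p = 0.00926). The overlap used the union of both H3K4me3 replicates of the same genotype and subset. Per gene, two-sided Fisher's exact tests compared 6 WT with 6 KO libraries, or 4 libraries of a subset with the 8 others, over genes present in 2 to 10 of 12 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Loss of H3K4me3 at CFP1-bound genes was measured per pair of subset and replicate number as a log2 odds ratio, with 0.5 added to each cell, and tested by an exact two-sided sign-flip over the 6 pairs. The 22 gene lists (327 genes, all found in the table) were compared by members present per library with the same permutation, adjusted over the lists, and against 10000 random lists matched on the number of libraries with a peak (seed 11). Further library measures (covered length, genes per library and share of peaks at gene ends) were computed beside the planned ones, 6 for CFP1 and 5 for H3K4me3. The computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

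Genes were named by a rule: Cxxc1; list members that differed by 3 or more libraries between genotypes or were among the 4 with the largest difference in a list; per antibody the 10 genes with the largest excess of WT and of KO libraries; per subset the 5 genes with the largest difference in H3K4me3; and the 5 strongest WT CFP1 genes by within-list rank of fold enrichment. Ties went to the higher median rank, and predicted genes were passed over. Some genes that meet the rule are not named here, and group values include every member. The groups, tests, lists, naming rule and the alternatives not said to be chosen later were fixed before the data were examined.

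The tests were run on simulated data drawn from the real presence rates. With 200 genes made present in every WT and no KO library, 0% were recovered for CFP1 (median of 5387 genes tested) and 100% for H3K4me3 (1826 genes). With 400 such genes 100% were recovered for CFP1. At a presence of 95% in WT and 5% in KO, recovery of 200 genes was 54.8% for H3K4me3, and recovery of 400 genes was 0% for CFP1.

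Replicate numbers come from the sample titles and are shared by all groups. For H3K4me3, the deviations from the subset mean of the WT and KO libraries of one number correlated across genes at 0.109 in CCR6+, 0.166 in NKp46+ and 0.283 in DN cells for presence, the quantity tested, and at 0.566, 0.615 and 0.663 for within-list ranks. All 3 exceeded 0.1, so the numbers were taken to pair the H3K4me3 libraries, and splits of the samples were compared among those that part all 6 pairs. Results with the replicate number as a block had been seen before this choice was written down.

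The alternatives were: peaks with q of 0.001 or less, or fold enrichment of 5 or more; windows of 500 b and 3000 b; the summit inside the window; all annotated genes; all sequences; lists of equal length; another overlap rule; stratification by H3K4me3 quintile; CFP1-bound genes without a KO peak; a permutation test per gene; the replicate number as a block; and each library or replicate left out. Chosen after seeing the data were the end of each gene that carries H3K4me3, the whole gene with 1000 b on each side, CFP1 without KO NKp46+ and KO DN of replicate 2, and H3K4me3 without the 3 WT libraries of replicate 2. Peaks on other sequences were left out of the comparisons and are described in the closing section.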

Results

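Group 3 innate lymphoid cells (ILC3s) are tissue-resident lymphocytes that produce interleukin-22 and interleukin-17. They were sorted from the small intestine of mice, given as 6 to 8 weeks old in the sample labels, into a CCR6+, an NKp46+ and a DN subset. Cells with floxed Cxxc1 alleles and no Cre (here WT) were compared with cells in which a Cre acts on those alleles (here KO). Cxxc1 encodes CFP1, a protein that binds unmethylated CpG DNA and belongs to the SET1 complexes, which methylate lysine 4 of histone H3. CUT&Tag, in which an antibody directs a transposase to the chromatin it recognises, was run with an antibody to CFP1 and with an antibody to trimethylated lysine 4 (H3K4me3), a mark of active gene starts. The 24 libraries fell into 12 groups of 2, with 1 deposited peak list per library. The lists carry no read counts, so the sequencing depth behind each list is unknown. On the 19 autosomes and the X chromosome, CFP1 lists held 714 to 8881 peaks and H3K4me3 lists 11794 to 18127 peaks.

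The first comparison asked whether CFP1 binding was lost in the KO cells. In CCR6+ cells the WT libraries held 5226 and 7983 CFP1 peaks and the KO libraries 1312 and 1250. In NKp46+ cells the WT libraries held 4749 and 5526 CFP1 peaks, against 714 in KO replicate 1 and 4891 in KO replicate 2. In DN cells the WT libraries held 4574 and 7703, against 1131 and 8881. KO lists were thus shorter in 5 of 6 pairs of subset and replicate number, and the KO to WT log2 ratio averaged −1.56 ± 0.52 (SE over 6 pairs), with 2.96-fold more peaks in WT. An exact two-sided permutation test of the genotype labels within subsets gave p = 0.0741, so the difference over all 12 libraries did not pass the threshold. Counted as genes with CFP1 per library, the log2 ratio was −1.57, with an exact permutation p of 0.0278 before and 0.148 after adjustment over the 6 measures computed for CFP1. The mean log2 ratio was −2.25 in replicate 1, with 3 of 3 pairs lower in KO, and −0.88 in replicate 2, with 2 of 3 pairs lower. Leaving out KO DN replicate 2 gave −2.06 (exact permutation p = 0.0185) and leaving out KO NKp46+ replicate 2 gave −2.03 (p = 0.0278). Without both, which were picked after their peak numbers were seen, the ratio was −2.52 (exact permutation p = 0.0185), and with peaks of fold enrichment 5 or more it was −1.71 (p = 0.037).

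**Figure D1:**
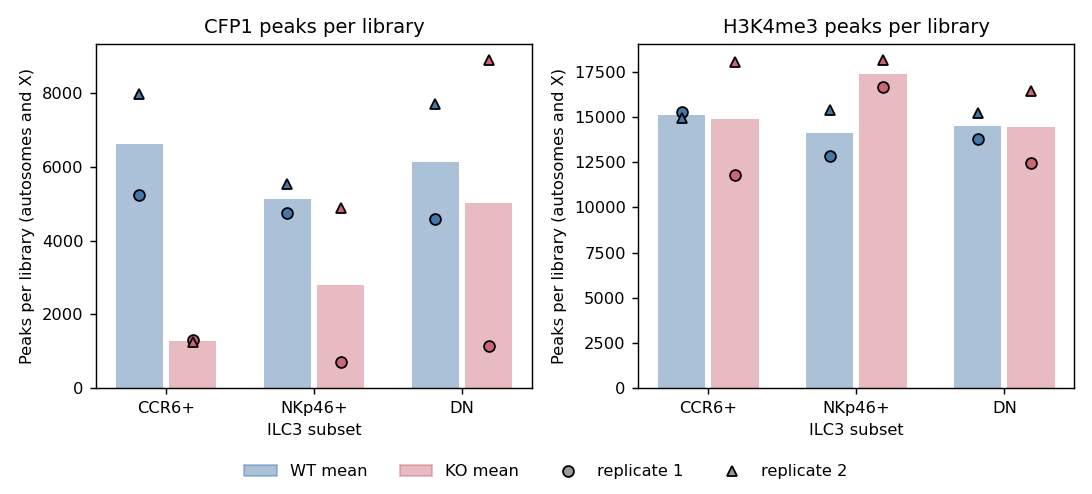
Peaks per library on the autosomes and the X chromosome for CFP1 (left panel) and H3K4me3 (right panel), by ILC3 subset on the x axis. Bars are means of 2 libraries, circles replicate 1 and triangles replicate 2; the KO CFP1 lists lie between 714 and 1312 peaks except replicate 2 of NKp46+ (4891) and DN (8881).

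At Cxxc1 itself (chromosome 18, 74216212 to 74221493, mm10), a CFP1 peak at 74215982 to 74216516 was listed in 2 of 6 WT libraries, both of replicate 1, and in 0 of 6 KO libraries. H3K4me3 marked the same gene end (74215794 to 74217154) in all 6 WT and all 6 KO libraries, which does not check the deletion, since the deleted part of the gene is not named in the labels.

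The next comparison asked which genes carried CFP1 in WT and not in KO cells, with a gene counted where a peak touched the window of 1000 b on either side of an annotated gene end. CFP1 was listed in all 6 WT and 0 of 6 KO libraries at 56 protein-coding genes, and in 0 WT and all 6 KO libraries at 0 genes. Among those 56 by within-list rank were Zfp959, a zinc finger gene (peak on chromosome 17, 55891755 to 55892462), Mios, a subunit of the GATOR2 complex that signals amino acids to mTORC1 (chromosome 6, 8208889 to 8209770), Cmpk1, a nucleotide monophosphate kinase (chromosome 4, 114986623 to 114987196), and the phosphatase gene Ppp5c (chromosome 7, 17027074 to 17027928). Atxn7l3b, Agbl3, Cep85l and Tmem33 had the same pattern, as did Fancm, a DNA repair helicase, and its neighbour Fkbp3, which share 1 peak (chromosome 12, 65073491 to 65074076). The Zfp959 peak lay inside the gene, and with a window of 500 b the difference there was 0 libraries. Of 5741 genes with CFP1 in 2 to 10 of the 12 libraries, 0 differed between genotypes after Benjamini-Hochberg adjustment of two-sided Fisher's exact tests (smallest adjusted p = 0.202). At an unadjusted p under 0.05 there were 431 genes, all with fewer KO than WT libraries, and the same number with an exact permutation within subsets. Genes in all 6 WT and no KO libraries reach an exact p of 0.00216, and 249 of them would have been needed for an adjusted p under 0.05. Without KO DN replicate 2 the adjusted count was 267 genes, and without KO NKp46+ replicate 2 as well, both picked after seeing the data, it was 747. The unadjusted count was 1279 without KO DN replicate 2, 927 without KO NKp46+ replicate 2 and 714 without WT NKp46+ replicate 2.

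The genes with more KO than WT libraries differed by at most 2 libraries. They included Lilrb4a, an inhibitory receptor, Gas1, Ccng1, Smyd3 and Smug1, each with 0 WT and 2 KO libraries, and Rassf8 with 1 WT and 3 KO libraries. Zfp948, Bfsp2 and Pbx4 also had 0 WT and 2 KO libraries, as had Abcb9, whose direction turned to 1 library fewer in KO when the whole gene was searched. In every one of these genes with 0 WT libraries, the KO libraries were NKp46+ and DN of replicate 2. The strongest WT CFP1 sites by within-list rank were H2az2, a histone variant gene (chromosome 11, 6443902 to 6444766), Gbe1, the glycogen branching enzyme (chromosome 16, 70313848 to 70314504), and Azi2 with Zcwpw2, which share a peak (chromosome 9, 118040258 to 118041034). A CFP1 peak was listed at these 4 genes in all 12 libraries, and at Ensa (chromosome 3, 95624794 to 95625430) in 6 WT and 5 KO libraries. With no control library known, the KO peaks there may be background, which was not tested.

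Within subsets, CFP1 was present in both WT and neither KO library at 2333 genes in CCR6+, 806 in NKp46+ and 373 in DN cells. The reverse, both KO and neither WT, held for 0, 1 and 12 genes. Of these genes, 56 had that pattern in all 3 subsets and 621 in 2 or more. In DN cells 897 genes held CFP1 in both replicate 2 libraries and neither of replicate 1, more than the 373 that followed genotype, and in NKp46+ cells the number was 315. With 2 libraries against 2 the smallest possible exact p is 0.333, so these counts carry no test. Within replicates 1 and 2, the genes with CFP1 in WT and not in KO numbered 3693 and 4288 in CCR6+, 3976 and 1250 in NKp46+, and 3362 and 815 in DN cells. Single libraries moved the counts too: NKp46+ to 2416 without KO and 2103 without WT of replicate 2, and DN to 2477 without KO of replicate 2 and to 761 and 957 without WT of replicates 1 and 2.

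Gene groups fixed in advance were compared by the number of members with CFP1 per library. The SET1/MLL complexes and H3K4 demethylases held CFP1 at 12.2 ± 2.04 (SD, n = 6) of 20 members in WT and 4.33 ± 4.13 in KO libraries (exact permutation p = 0.0278). Setd1a, a catalytic subunit of the complex CFP1 belongs to, and its partners Rbbp5, Wdr82 and Hcfc1 each had 6 WT and 2 KO libraries, and Kmt2a, a related methyltransferase, had 5 and 0. KLF factors and quiescence genes held it at 11.7 ± 1.63 and 5.33 ± 3.72 of 15 members (exact permutation p = 0.0278), with Foxp1 and Btg1, which restrain proliferation, at 6 and 1 libraries and Foxo1 at 4 and 0. Cell cycle genes held it at 8.83 ± 1.47 and 4.33 ± 3.39 of 24 members (exact permutation p = 0.0463), with E2f1 at 5 and 1 and the inhibitor Cdkn1b at 6 and 2. Housekeeping genes held it at 8.17 ± 1.17 and 3.83 ± 2.93 of 15 (exact permutation p = 0.037), with Hprt at 5 and 0. In the same order of WT and KO, AP-1 and MAPK genes had 12.5 and 6.83 of 20 (Mapk8 6 and 1), mitochondrial and metabolic genes 10.8 and 4.33 of 18 (Mtor and Cs 6 and 2), circadian clock genes 8 and 4.17 of 14 (Per1 and Per2 6 and 2), and m6A RNA enzymes 6 and 3.17 of 9 (Alkbh5 6 and 2), with exact permutation p from 0.0556 to 0.0741. Survival and apoptosis genes had 7.33 and 4 of 20 (Casp9 6 and 3, exact permutation p = 0.222). Within replicates 1 and 2, KO less WT was −10.3 and −5.33 members for the SET1/MLL group, −7.67 and −5 for the KLF group, −6.67 and −2.33 for the cell cycle and −5.67 and −3 for housekeeping genes. Among 10000 random lists matched on the number of libraries with CFP1, the excess of WT over KO lay at percentile 91.9 for the SET1/MLL group, 80.9 for the KLF group, 47.2 for the cell cycle, 29.4 for housekeeping, 14.02 for AP-1 and MAPK, 25.5 for mitochondrial and metabolic and 9.57 for circadian clock genes, and 72.98 for m6A RNA enzymes. Survival genes (0.95) and NKp46+ markers (0.505) lay at the low end, with a smaller excess of WT than nearly all matched lists.

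ILC3 transcription factors held CFP1 at 6.5 of 20 members in WT and 3.33 in KO, with Ahr, a sensor of dietary and microbial ligands, at 5 and 1 libraries, Cbfb at 6 and 2, and Maf and Zfp36l2 at 6 and 3. ILC3 effectors and receptors had 4.5 and 2 of 20, with Il10rb, a subunit of the interleukin-22 and interleukin-10 receptors whose window also touches Ifnar2, at 6 and 1. CCR6+ markers had 3.33 and 1.67 of 14 and NKp46+ markers 1 and 1 of 15. T cell markers had 1.17 and 1.33 of 12, with a CFP1 peak listed at Cd3d in all 12 libraries. Tissue-restricted genes had 0.333 and 0.167 of 15, and myeloid markers 0.167 and 0.167 of 13. NK and ILC1 markers had 0 and 0.167 of 10 and epithelial markers 0 and 0.167 of 12. Silent developmental genes, B cell, ILC2 and stromal and endothelial markers had 0 in every library. After Benjamini-Hochberg adjustment over the 22 groups, 0 passed the exact permutation test (smallest adjusted p = 0.204), and 0 single members passed when adjusted over the list alone. The smallest p that this design allows is 0.00926, which 5 groups would have had to reach, and without KO DN replicate 2 the count of groups that passed was 9, or 10 without KO NKp46+ replicate 2 as well, both picked after seeing the data.

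A further comparison asked where CFP1 sat relative to H3K4me3. In WT cells, 99.9% of the 3945 genes with CFP1 in both CCR6+ libraries also carried H3K4me3 in both, as did 99.9% of 3047 genes in NKp46+ and 99.9% of 3573 in DN cells. Of the H3K4me3-marked genes, 37.7%, 31.1% and 34.9% held CFP1 in these subsets. Counted by peak, 89.9% ± 8.87 (SD, n = 6) of CFP1 peaks overlapped H3K4me3 of the same genotype and subset in WT and 89.6% ± 9.70 in KO. The difference of −0.24 percentage points was smaller than the spread between libraries (exact permutation p = 0.944), and ran from −4.08 to 3.59 points when libraries were left out. The spread lay largely between replicate numbers, with 96.5% to 98.9% in libraries of replicate 1 and 75.6% to 85.5% in those of replicate 2. Within replicate 1 the KO to WT difference was 0.217 points and within replicate 2 it was −0.702 points.

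For H3K4me3, the peak lists of KO cells were about as long as those of WT cells. WT lists averaged 14571 ± 1035 peaks (SD, n = 6) and KO lists 15576 ± 2774, with a log2 ratio of 0.08 ± 0.12 (SE over 6 pairs, exact permutation p = 0.583). The KO list was longer in 4 of 6 pairs, all 3 of replicate 2 and NKp46+ of replicate 1. Median peak width was 1048 ± 161 b in WT and 969 ± 157 b in KO, a log2 ratio of −0.11 (exact permutation p = 0.472), and the lists covered 16.4 ± 3.39 and 16.2 ± 5.00 Mb. The mean log2 ratio of peak numbers was −0.05 in replicate 1 and 0.21 in replicate 2, and that of widths −0.13 and −0.09; without KO CCR6+ of replicate 2 the ratio of peak numbers was −0.02.

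At single genes, H3K4me3 was listed in all 6 WT and 0 of 6 KO libraries at 4 genes. These were Nupr1, a stress-response gene (peak on chromosome 7, 126624869 to 126626056), Arg1, which encodes the arginine-degrading enzyme arginase 1 and is also a marker of ILC2s (chromosome 10, 24925377 to 24928228), Serinc2 (chromosome 4, 130276529 to 130279419) and Adgrg3, an adhesion G protein-coupled receptor gene (chromosome 8, 95017445 to 95018587). Peaks elsewhere in the gene remained in 3 KO libraries at Serinc2 and 4 at Adgrg3. Il23r, a subunit of the interleukin-23 receptor (chromosome 6, 67489198 to 67492206), Mrc2, a collagen receptor (chromosome 11, 105292241 to 105293988), Cyp4f16, Ucp3 and Pdgfrb, whose window also touches a predicted gene, had 6 WT and 1 KO libraries. Slc6a13, a GABA transporter gene, had 5 and 0. With the whole gene searched, peaks were listed in 4 KO libraries at Ucp3 and 2 at Slc6a13. In the other direction Jag2, a Notch ligand gene (chromosome 12, 112928527 to 112930337), had 0 WT and 6 KO libraries, and Sun3, Stox1 and Rimkla had 1 and 6. Lama5, which encodes a laminin chain, Fcrlb, Hs3st6, Pdzd2 and Tnrc6a had 0 and 5, but with the whole gene searched Tnrc6a and Stox1 showed 0 difference and Pdzd2 turned to 1 library fewer in KO. At Fcrlb the difference was 1 library with a window of 500 b and 0 with the peak summit required in the window.

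Of 1877 genes with H3K4me3 in 2 to 10 libraries, 0 passed Benjamini-Hochberg adjusted Fisher's exact tests (smallest adjusted p = 0.769), and 82 genes as complete as Arg1 would have been needed. At an unadjusted p under 0.05 there were 35 genes by Fisher's exact test and by an exact permutation within subsets, 15 with fewer and 20 with more KO libraries. With the replicate number as a block the count was 5. Only genes in all libraries of 1 genotype and none of the other can reach that threshold there. Without KO CCR6+ or KO DN of replicate 1 the count was 131 or 137. H3K4me3 was present in all 12 libraries at 9253 genes.

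**Figure D2:**
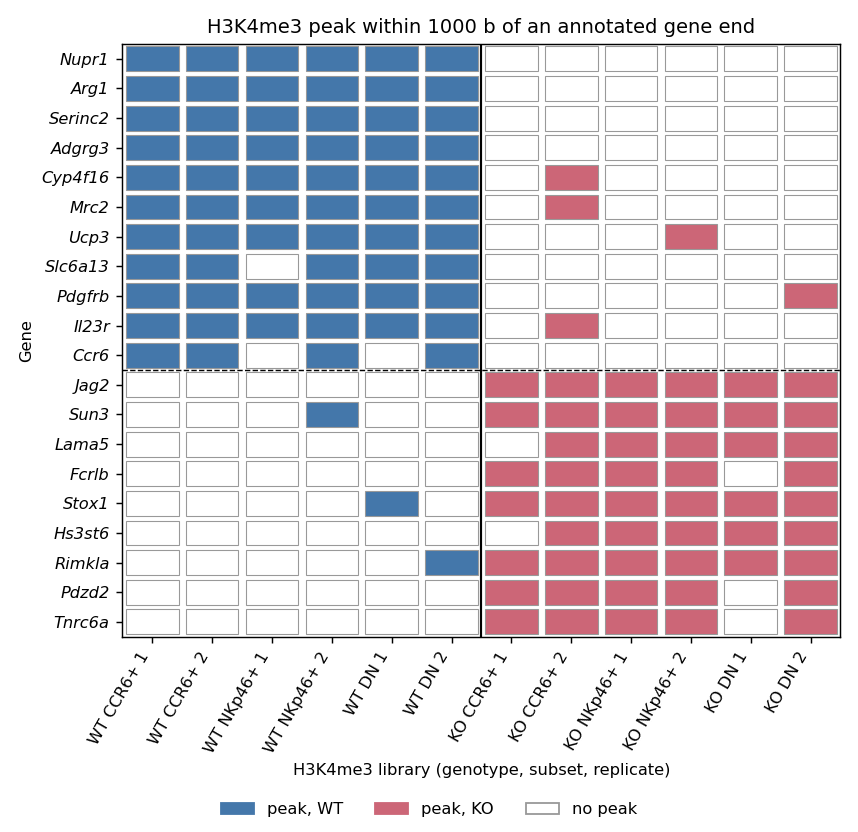
Presence (filled) or absence (white) of an H3K4me3 peak within 1000 b of an annotated gene end in the 12 H3K4me3 libraries (columns), for genes named by rule (rows): above the dashed line the 10 genes with the largest excess of WT libraries plus Ccr6, below it 9 genes with a large excess of KO libraries. Nupr1, Arg1, Serinc2 and Adgrg3 are filled in 6 WT and 0 KO libraries and Jag2 in 0 WT and 6 KO libraries.

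Gene groups were compared for H3K4me3 in the same way. ILC3 effectors and receptors were marked at 16.2 ± 0.41 (SD, n = 6) of 20 members in WT and 13.2 ± 2.14 in KO libraries (exact permutation p = 0.00926, the smallest this design allows, adjusted p = 0.204 over 22 groups). With the replicate block the exact permutation p was 0.0312, the smallest possible there, and the adjusted p 0.344. In this group 8 members had fewer KO than WT libraries, 0 had more, and 12 were equal. Il23r had 6 and 1 libraries, the interleukin-2 receptor gene Il2ra and the lymphotoxin gene Lta 6 and 3, and Csf2, which encodes GM-CSF, 6 and 4. At Lta and Csf2 the KO libraries without a peak were all of replicate 1. The difference of the group was larger than in 100% of 10000 random lists matched on the number of marked libraries, but CCR6+ markers (percentile 99.9), T cell markers (99.8), ILC2 markers (98.7), NKp46+ markers (98.7), circadian clock genes (98.6) and ILC3 transcription factors (96.8) also lay high among their matched lists. For circadian clock genes and ILC3 transcription factors this rests on the same 1 gene with fewer KO libraries. In each, 1 other member had more and the rest were equal. For the effectors and receptors, KO less WT was −4.67 members in replicate 1 and −1.33 in replicate 2. The unadjusted p was above 0.05 without WT CCR6+ of replicate 1 (exact permutation p = 0.0556) or of replicate 2 (p = 0.0926), and with peaks of fold enrichment 5 or more (p = 0.102). CCR6+ markers were marked at 10.5 and 8.67 of 14 members, with Ccr6 itself at 4 WT and 0 KO libraries and Cxcr5 at 6 and 3 (exact permutation p = 0.157, or 0.0312 with the replicate block, adjusted p = 0.611 and 0.344). The KO libraries without a peak at Cxcr5 were all of replicate 1. NKp46+ markers were marked at 10.2 and 8.83 of 15, with Ncr1, the gene for NKp46, at 4 and 2 and Klrb1c at 3 and 1. In NKp46+ cells themselves, Ncr1 was marked in every WT and KO library and Klrb1c in replicate 2 of both genotypes. The WT excess at both genes came from the CCR6+ and DN libraries of replicate 2. ILC3 transcription factors were marked at 16.7 and 16 of 20. In this group 1 member had fewer KO than WT libraries and 1 had more, the latter being Nfil3 at 5 and 6 libraries.

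Markers of other cell types were followed beside these groups. T cell markers were marked at 10.3 ± 2.25 of 12 in WT and 7.83 ± 3.60 in KO libraries (exact permutation p = 0.194), with Cd8b1 at 5 and 1 libraries and Cd28 at 6 and 4. Myeloid markers moved the other way at 1.5 and 3.17 of 13 (exact permutation p = 0.185), with Spi1 at 0 and 2. ILC2 markers had 4 and 3.17 of 10, NK and ILC1 markers 4 and 3.83 of 10, and B cell markers 1.67 and 1.17 of 10, with Blk at 5 and 1. Epithelial markers had 2 and 3 of 12, with Krt18 at 0 and 3, and stromal and endothelial markers 2.17 and 2 of 12, with Pdgfrb at 6 and 1 and Pecam1 at 4 and 1, and in the other direction Col1a1 at 3 and 6 and Kdr at 0 and 3. Silent developmental genes had 0.167 and 1 of 15, with Foxa2 at 1 and 4. Circadian clock genes had 11.8 and 11.2 of 14, cell cycle genes 21.7 and 22 of 24, survival and apoptosis genes 16.5 and 16.7 of 20, and KLF factors and quiescence genes 13.8 and 14 of 15. The groups with the same number in every library were the SET1/MLL complexes (17 of 20), AP-1 and MAPK genes (18 of 20), mitochondrial and metabolic genes (16 of 18), m6A RNA enzymes (8 of 9), housekeeping genes (13 of 15) and tissue-restricted genes (2 of 15). Of the 22 groups, 0 passed the adjusted threshold, with 1 group at an unadjusted p under 0.05. In Fisher's exact tests adjusted over the list alone, Arg1 passed among the ILC2 markers (adjusted p = 0.00649). So did 1 member, not named here, of the ILC3 transcription factors and 1 of the circadian clock genes. Each was the only member tested in its group.

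Within subsets, H3K4me3 was present in both WT and neither KO library at 39 genes in CCR6+, 19 in NKp46+ and 31 in DN cells, and in both KO and neither WT library at 34, 408 and 31 genes. On lists of equal length the WT pattern held at 91, 163 and 61 genes. In NKp46+ cells, where the KO genes were the more numerous, both KO lists (16635 and 18127 peaks) were longer than both WT lists (12838 and 15397). The WT pattern held in 2 or more subsets at 18 genes and in all 3 at 4, which are Nupr1, Arg1, Serinc2 and Adgrg3. Il23r, Mrc2, Ucp3, Cyp4f16, Pdgfrb and Slc6a13 were among the 18. Replicate number parted more genes than genotype did in CCR6+ and DN cells, with 224 and 284 genes marked in both replicate 2 libraries and neither of replicate 1, and 151 in NKp46+ cells. Within replicates 1 and 2, genes with H3K4me3 in WT and not in KO numbered 883 and 94 in CCR6+, 69 and 141 in NKp46+, and 562 and 110 in DN cells. The CCR6+ count was 730 without KO of replicate 2 and 90 and 77 without WT of replicates 1 and 2, the DN count 494, 105 and 50 in the same order, and the NKp46+ count 62 without KO of replicate 2 and 130 without WT of replicate 1.

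The last genotype comparison asked whether H3K4me3 was lost in KO cells where WT cells carried CFP1. Loss here means that no peak was called, so a fall of signal at a peak that is still called is not registered. Counted in this way, loss was rarer at CFP1-bound than at unbound genes in all 6 pairs of subset and replicate number. In CCR6+ cells of replicate 1, H3K4me3 present in WT was missing in KO at 10 of 3943 genes with CFP1 in both WT libraries (0.254%, Wilson 95% confidence interval 0.138% to 0.466%) and at 781 of 4489 genes with CFP1 in neither (17.4%, 16.3% to 18.5%). In NKp46+ cells of replicate 1 the shares were 1 of 3046 (0.0328%) and 65 of 4491 (1.45%), and in DN cells 5 of 3573 (0.14%) and 516 of 4567 (11.3%). In replicate 2 the CFP1-bound genes lost H3K4me3 at 0 of 3941 in CCR6+, 0 of 3045 in NKp46+ and 0 of 3571 in DN cells. The floors (3 counts of the total) were 0.0761%, 0.0985% and 0.084%, and the Wilson 95% upper limits 0.0974%, 0.126% and 0.107%. The unbound genes of replicate 2 lost it at 1.95%, 2.61% and 2.19%. The log2 odds ratio of loss averaged −6.59 (SD 0.96, 6 pairs), with an exact two-sided sign-flip p of 0.0312, the smallest that 6 pairs allow. Stratified by quintile of the WT fold enrichment it was −4.39 (p = 0.0312 in the same exact test), and on H3K4me3 lists of equal length −3.06 (p = 0.0312). Leaving out any single H3K4me3 library leaves 5 pairs, for which the exact p cannot fall below 0.0625, with the ratio at −6.93 to −6.44. CFP1-bound genes ranked higher in WT H3K4me3 in all 3 subsets, with a median percentile of 66.5 against 59.6 in CCR6+ cells. They may therefore be missed less often between any 2 lists, and no WT lists were compared with each other in this way. The ratio thus cannot be tied to the loss of CFP1. In replicate 2 the KO CFP1 lists of NKp46+ (4891 peaks) and DN cells (8881) were also as long as WT lists.

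**Figure D3:**
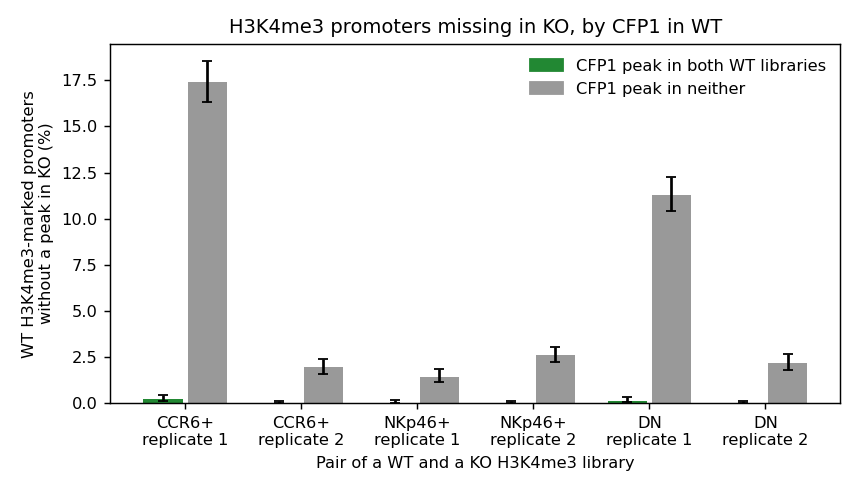
Share (%) of genes with H3K4me3 in a WT library that lack it in the KO library of the same subset and replicate number, for genes with CFP1 in both WT libraries (green) and in neither (grey). Error bars are Wilson 95% confidence intervals; the CFP1-bound share is at most 0.254% in all 6 pairs and the unbound share runs from 1.45% to 17.4%.

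The sorted subsets were compared with each other over both genotypes, 4 libraries against 8. In DN cells H3K4me3 marked Cd5, a surface glycoprotein of T cells and some B cells (chromosome 19, 10738061 to 10739037), and Nr2e3 in 4 of 4 libraries and in 0 of 8 others, and Ankrd29 in 4 and 1. In CCR6+ cells it marked Tlr4, the lipopolysaccharide receptor (chromosome 4, 66827224 to 66828752), in 4 of 4 and 0 of 8 and Rnf180 in 4 and 1. Arhgap28 had 4 and 2, and Cacnb2 and Col4a5 3 and 0. In NKp46+ cells it marked Krt83 in 4 of 4 and 1 of 8, and Xcl1, a chemokine of cytotoxic lymphocytes (chromosome 1, 164933584 to 164936024), in 4 and 2. Oacyl, Aoah, an enzyme that inactivates lipopolysaccharide, and Pglyrp1 had 3 and 0. St6galnac2 and Dlg3 had 4 and 2 in DN cells. Of 1877 genes tested per subset, 0 passed Benjamini-Hochberg adjusted Fisher's exact tests (smallest adjusted p = 1), and 18, 12 and 14 had an unadjusted p under 0.05 in CCR6+, NKp46+ and DN cells. The smallest exact p is 0.00202 here, which 76 genes would have had to reach.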

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

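Chosen only after the result was seen were the tests of exchanged labels, of CFP1 left in 2 subsets, of shorter KO lists and of myeloid cells, the splits of CFP1 libraries that part all pairs, the balanced splits by subset, and the spread criterion in the test of CFP1 binding at effector genes.

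Peaks outside the comparisons stood out in every library as signal in data not analysed above. On one unplaced scaffold the median was 26.5 peaks per library, 16 to 33 over all 24 libraries, and on the mitochondrial genome it was 4, with 2 to 6 per library. No library lay apart from the other 5 of its antibody and genotype by Dixon's criterion in 26 sets of values, and none of 171 comparisons of subsets moved in opposite directions in every library.

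The CFP1 lists of KO NKp46+ and KO DN of replicate 2, with 4891 and 8881 peaks, were as long as WT lists, unlike the 714 to 1312 peaks of the other 4 KO lists. An exchange of labels with a WT CFP1 library is argued against, since the shortest WT list held 2.63 times as many genes as the longest of those 4 KO lists, but a single wrong label or an exchange with an outside sample stays open. CFP1 left in KO NKp46+ and DN cells in general is argued against by replicate 1, where the mean KO to WT log2 ratio was −2.37 in these subsets and −1.99 in CCR6+ cells, a difference of −0.38; incomplete deletion in the animals of replicate 2 may still account for the lists and was not tested. Background sites reached by longer lists cannot be told apart from CFP1 binding: among the top 1250 peaks, the genes of these lists overlapped those of KO CCR6+ of replicate 2 with a Jaccard index of 0.349, against 0.513 with WT lists and 0.307 for WT lists with KO CCR6+. That comparison stays open because depth is unknown and each index rests on 1 to 3 lists.

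H3K4me3 at genes marked in 1 subset in replicate 1 was less restricted in replicate 2. Of 40 such genes, the share marked in the same subset exceeded the share in the other subsets by 43.75 percentage points in WT and 33.75 in KO libraries of replicate 2. Complete mixing of subsets in the WT samples of replicate 2 is argued against by that 43.75. The contrast was set to fall under 10 if they were mixed. Partial mixing stays open, since it need not bring the contrast under 10. At Ncr1, Klrb1c and Ccr6, chosen after their values were seen, every WT library of replicate 2 held H3K4me3. Among KO libraries of replicate 2, Ncr1 and Klrb1c held it only in NKp46+ cells and Ccr6 in none. Tlr4 and Cd5, in contrast, kept to CCR6+ and to DN cells in both genotypes of replicate 2. Longer lists that reach weak peaks of every subset may account for the lower restriction of the 40 genes. The KO lists of replicate 2 were longer than the WT lists and their contrast was lower, by −10 points. Choosing the genes on replicate 1 alone would also lower their contrast in replicate 2, which was not tested, nor was any biological explanation.

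ILC3 effector genes such as Il23r, Il2ra and Lta held H3K4me3 in fewer KO than WT libraries. At Lta the KO libraries without it were all of replicate 1. Shorter KO lists as the only cause are argued against. In each of the 4 pairs with the longer KO list, KO held fewer effector genes (mean difference −2, SD 1.41). In CCR6+ and DN cells of replicate 1, where the KO list was shorter, the number fell from 16 to 10 and from 16 to 12. List length may thus add to the difference, which was not tested. Myeloid cells in the KO samples are argued against, since 6 abundant myeloid genes (Lyz2, Csf1r, Cd68, Fcgr1, Itgam and Adgre1) held H3K4me3 in a mean of 0.5 of 6 KO libraries. Loss of CFP1 binding at these promoters stays open: 12.5% of them (1 of 8) held CFP1 in both WT libraries of a subset, against 41.3% of marked genes, with too few genes to tell (exact binomial p = 0.152). A change in which ILC3s fill each sorted gate may also account for the pattern and was not tested.

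Other splits of the 12 libraries were used to ask whether chance can be excluded. For the 431 CFP1 genes at an unadjusted p under 0.05 chance is argued against but not excluded. Of 100 drawn splits, which set aside subset and replicate number, 2 gave as many, the real one included. The highest other, 442, set 5 KO libraries and 1 WT library against the rest. Among the 32 splits that part same-numbered WT and KO libraries, only the real one (1) gave as many, with 342 as the highest other. That is the smallest share these splits can give. The gene count may also follow list length, and CFP1 peak numbers gave p = 0.0741 in the exact permutation test. For the adjusted CFP1 count of 0, all 100 splits gave as many, and the highest other was 0. Among the 32 splits that part all 6 pairs of H3K4me3 libraries, 2 gave at least the 35 unadjusted genes, with 39 as the highest other, so chance is not excluded; all 32 gave at least the adjusted count of 0, with 0 as the highest other. Splitting the libraries by replicate number gave 99 unadjusted genes for H3K4me3, more than genotype, and 114 for CFP1, fewer than genotype. Genotype with the replicate block gave 5 for H3K4me3, a count that cannot be compared with the 99. Under the block only genes in all 6 libraries of 1 genotype and none of the other reach a p under 0.05.

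For the genes that set a subset apart in H3K4me3, freely drawn splits do not exclude chance. As many unadjusted genes came from 12 of 100 drawn splits for CCR6+ (18 genes, highest other 128), 22 for NKp46+ (12 genes, highest other 305) and 21 for DN (14 genes, highest other 149). The split with 305 set apart the 4 longest lists, all KO and mostly of replicate 2, and gave 87 genes at an adjusted p under 0.05. List length, genotype and replicate number cannot be told apart in that split. A sorted subset, with 1 library per genotype and replicate, cannot hold such a set of lists. Among the 81 splits balanced in that way, chosen after the free splits were seen, as many genes came from 2 for CCR6+, 5 for NKp46+ and 3 for DN, with 22 as the highest other each time. On these splits the share that gave as many was under 0.05 for CCR6+ and DN cells and not for NKp46+ cells, without adjustment for the 3 subsets. Chance is not taken as excluded, since the planned free splits did not exclude it and a split of mixed subsets gave 22 genes.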

How the results depend on the processing

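The runs without the doubted libraries, at the marked gene end and over the whole gene were chosen after seeing the data; all others were planned. Of 942 recomputed values, 774 kept their direction and their side of the threshold, or for counts stayed within 1.5 times. The limits are the unknown depth, the presence of a peak as the measure, and 2 libraries per group; where values changed, the cause was not tested unless fewer libraries or pairs are named.

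The CFP1 peak ratio passed the threshold with peaks of fold enrichment 5 or more (−1.71) and without KO NKp46+ and KO DN of replicate 2 (−2.52). Without those libraries, 747 genes and 10 gene groups passed for CFP1, CFP1 was present in both WT and no remaining KO library at 2416 genes in NKp46+ and 2477 in DN cells, and the overlap of CFP1 peaks with H3K4me3 turned to 5.54 percentage points higher in KO. H3K4me3 genes in both WT and neither KO library of CCR6+, NKp46+ and DN cells numbered 89, 30 and 56 with all annotated genes, which adds genes, and 91, 163 and 61 on lists of equal length. Without the 3 WT libraries of replicate 2 they numbered 77 in CCR6+ and 50 in DN cells, the log2 ratio of median width turned to 0.0768, and the log2 odds ratio was −5.86 with an exact sign-flip p of 0.25, the smallest that 3 pairs allow. With the whole gene searched, KO less WT turned to −1 library at Abcb9 for CFP1 and at Pdzd2 for H3K4me3.

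Leaving out libraries or replicates gave ranges of −2.25 to −0.88 for the CFP1 peak ratio, −0.0488 to 0.21 for the H3K4me3 peak ratio, −4.08 to 3.59 points for the overlap, and −6.93 to −4.77 for the odds ratio, whose p was above the threshold with 5 or 3 pairs. Genes with CFP1 in both WT and neither KO library ran from 2333 to 4288 in CCR6+, 806 to 3976 in NKp46+ and 373 to 3362 in DN cells, and those with H3K4me3 from 39 to 883, 19 to 141 and 31 to 562. CFP1 genes that passed ran from 0 to 267 and CFP1 groups from 0 to 9. H3K4me3 genes and groups, and genes set apart by a subset, stayed at 0 in all settings. Single groups were followed only where the unadjusted p was under 0.05: the 4 CFP1 groups and the ILC3 effectors kept their direction in 125 recomputed values and missed that threshold in 40.

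With the replicate number as a block, the CFP1 peak ratio of −1.56 had an exact permutation p of 0.0938, the unadjusted CFP1 genes went from 431 to 56, and 3 of the 4 CFP1 groups missed the unadjusted threshold (exact permutation p = 0.0625), where the smallest p is 0.0312. For single genes, only those in all libraries of 1 genotype and none of the other reach that smallest p, and these are the 56. In turn, CFP1 at the ILC3 effectors and receptors went from an exact permutation p of 0.157 to 0.0312. The counts of adjusted CFP1 genes and groups stayed at 0. For H3K4me3 the block changed no call beyond the values given with the results. For CFP1, the deviations of same-numbered WT and KO libraries correlated at 0.0395, 0.0744 and 0.203 for presence in CCR6+, NKp46+ and DN cells, and at 0.192, 0.295 and 0.313 for ranks, so by presence the numbers were not taken to pair the CFP1 libraries.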

Other observations

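The test of T cell markers was chosen after the result was seen; the other values here are descriptive.

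Among H3K4me3-marked genes of WT cells, those with CFP1 lay higher in the within-list rank of H3K4me3 fold enrichment than those without. The median rank percentile was 66.5 and 59.6 in CCR6+, 67.1 and 60.03 in NKp46+, and 67.1 and 58.5 in DN cells. Peaks in the KO CFP1 lists may be CFP1 or background, which the lists cannot tell apart. Genes with such a peak in both KO libraries also carried H3K4me3 at 467 of 468 in CCR6+ cells. The numbers were 619 of 620 genes in NKp46+ and 1113 of 1113 in DN cells. These genes ranked higher than the genes without CFP1 only in DN cells (67.9 and 63.0), with 63.1 and 64.3 in CCR6+ and 65.4 and 67.2 in NKp46+ cells. They made up 4.75%, 5.75% and 11.3% of the H3K4me3-marked genes of KO cells.

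Replicate number set the CFP1 lists apart in where peaks fell. Of the CFP1 peaks of replicate 1, 76.2% to 86.1% touched a gene-end window, and of replicate 2, 47.8% to 56.9%, in WT and KO libraries alike. Gene sets of WT CFP1 libraries overlapped with a median Jaccard index of 0.618, and those of KO libraries with 0.264. For H3K4me3, the median rank correlation across genes, which are not independent replicates, was 0.908 between libraries of one replicate number and 0.699 between numbers. No pair of libraries shared more than 251 identical peaks, so none was taken for a copy of another.

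A hypothesis is that T cells may be present among the sorted DN cells, whose gate the labels do not describe beyond its name. T cell markers held H3K4me3 at 10 to 12 of 12 genes in DN libraries, 4 to 11 in CCR6+ and 3 to 11 in NKp46+ libraries, and the difference of DN from the other subsets averaged 3.625 genes (exact permutation p = 0.0123, the smallest that 81 arrangements allow). B cell markers differed by −0.25 genes (exact permutation p = 0.741) and myeloid markers by −1.25 (p = 0.383). Cd3e, Cd3d and Lat, chosen after their values were seen, were marked in most libraries of every subset, so the test cannot separate T cells from ILC3s with marked T cell genes.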
